A study of Mus musculus with 18 samples.

How the data were processed

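RNA was measured in 18 libraries from mice that carried Tie2-cre and NuTRAP: input and positive (anti-GFP pull-down) fractions of choroid, retina and brain, with 3 libraries in each of the 6 groups. Groups and the replicate numbers 421, 953 and 960 were read from the sample titles. Per the labels, 2 eyes were pooled for each retina or choroid sample and 0.5 of a brain was used for each brain sample, the lysate was cleared at 12000 g, and 150 microlitres of supernatant were set aside as input. Sex and age are not given in the sources used here, and libraries without the transgenes or with a mock pull-down were not analysed here.

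The authors deposited 1 table per tissue. The raw columns hold expected counts per gene, deposited by the authors with fractions of a read (72.0% of values in choroid, 91.5% in retina and 90.2% in brain are not whole within 0.001), and they were rounded for the count models. The normalized columns are log2 values made by the authors: checked against the raw columns, they equal log2 of the raw value over 1 factor per library, minus the median of the 3 inputs of the tissue (99.99%, 99.97% and 99.99% of values within 0.001 in choroid, retina and brain). Per the file headers, a gene is listed where all libraries of at least 1 of the 2 fractions have a raw value of at least 50, and every listed gene met this. The tables held 11718 genes in choroid, 12369 in retina and 12919 in brain, 10505 of them in all 3 and 14068 in at least 1. The submitters' processing notes name DESeq and the genome build mm10, and the aligner and the counter are not given in the sources used here. Coordinates are those of the tables. Of the listed genes 13384 matched the reference annotation by Ensembl ID, 100% of them on the same chromosome and 86.6% with a start within 1000 bases. Genes under the header's minimum are missing from a table, so depth is the sum over listed genes: 8807306 to 14484068 counts per input and 2649095 to 4587921 per positive library in choroid, 15243098 to 21521130 and 6260958 to 11071373 in retina, and 9596740 to 32064355 and 18618427 to 28277853 in brain.

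Enrichment was tested in each tissue as positive against input with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, which removed no gene, quasi-likelihood F test, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment over the genes tested and a call at an adjusted p under 0.05. A gene was enriched where it was called higher with a log2 fold change of at least 1. Differences in enrichment between tissues were tested as the difference of the 2 log2 ratios in a fit of all 18 libraries (12 residual degrees of freedom), and positive fractions were compared in a fit of the 9 positive libraries (6 residual degrees of freedom), both over 10505 genes. CPM values in the enrichment comparisons are scaled within each tissue, and those in the comparisons between tissues over the 9 positive libraries. The tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined, and those chosen afterwards are named where their effect is given. Gene lists (44, for endothelial subtypes and pathways, for other cell types of these tissues and for housekeeping classes) held 624 members matched by symbol and 10 by Ensembl ID, with 60 in no table. Members shared between lists were left in each. Lists with at least 3 measured members were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over all lists and the 3 tissues or the 3 differences. With the preset correlation 52 list tests were called higher and 18 lower for enrichment and 8 and 29 for the differences. With the estimated correlation none was (0). That estimate rests on the few residual degrees of freedom of a fit (4 for enrichment and 12 for the differences). The smallest adjusted p it gave was 0.284 for enrichment and 0.155 for the differences, even for lists with every measured member called higher. A missing call in this repeat therefore cannot tell an unchanged list from a changed one. Values of list counts "adjusted over the list alone" apply Benjamini-Hochberg to the members only.

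Genes to name were drawn from a fixed rule: per tissue the 10 highest and the 10 lowest log2 fold changes among called genes with a mean of at least 10 CPM and no overlap between the positive and input libraries (6 and 6 per difference in enrichment, and 8 and 8 per comparison of positive fractions among genes also enriched over input in the tissue in which they were higher), the 4 called members of each list with the smallest adjusted p and up to 2 uncalled members with the highest level, and 13 markers fixed in advance, 1 of which is not reported here. From this pool the text names genes whose call did not depend on a single library, and it says so where a marker fixed in advance did.

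Whether the replicate number pairs libraries was checked once. Within a tissue, input and positive libraries with the same number came from the same lysate, and their deviations from the group mean correlated, across genes, at 0.632, 0.268 and 0.527 in choroid (421, 953, 960), at 0.087, 0.066 and 0.008 in retina and at 0.189, 0.034 and 0.089 in brain. Across tissues the correlations ran from -0.08 to 0.165, and the labels do not say that a number is 1 animal. Within a tissue the number thus pairs an input with its positive library, and across tissues it is not known to. The tests, fixed before the data were examined, did not use the number, since the labels state no block. A block on it was run as an alternative, and its value stands beside each enrichment result whose call it changed. For the differences in enrichment a block within each tissue was also run, and all 62 named values kept their call. The other alternatives were DESeq2 1.42.0 size factors, library size only, the Wald test of DESeq2, limma-voom, no filter on low counts, a mean of at least 10 CPM, removal of abundant classes, a 2-fold minimum, all 18 libraries in one fit, and each library and each replicate number left out. After the data were seen, the authors' own factors, limma on the deposited log2 values, fits of only 2 tissues, another reference library for TMM and fits without both fractions of 1 replicate number were added. The pseudocount alternatives were not used here, since the tables hold counts.

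The tests were first tested on simulated data with the real library sizes and 1 mean per gene over all libraries of a fit. In these, 100 genes changed 2-fold and 100 changed 4-fold, as many up as down, and libraries were drawn independently. In the real data 13.3% to 72.02% of genes were called, depending on the comparison. The rates below therefore need not hold for the real data, and they do not test the scaling or the pairing of libraries. Of the 2-fold and 4-fold changes, 25% and 93% were recovered for choroid (11718 genes), 83% and 100% for retina (12369 genes) and 27% and 94% for brain (12919 genes). For the differences in enrichment, over 10505 genes, 15% and 89% were recovered for retina against brain, 11% and 83% for choroid against brain and 23% and 81% for choroid against retina, and for the positive fractions 72% and 100%, 61% and 100%, and 63% and 99%. Of the calls made, unchanged genes were 7.8% in choroid, 5.2% in retina and 5.5% in brain, 5.5%, 6% and 8% for the differences in the order above, and 6.5%, 4.2% and 3% for the positive fractions, against the 5% aimed at. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.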

Results

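The series profiled endothelial RNA from 3 vascular beds of the mouse: the choroid (collected with the retinal pigment epithelium, RPE), the retina and the brain. The animals carried a Tie2-cre transgene, whose promoter is active in endothelial cells and also in cells of the blood lineage. They also carried the NuTRAP allele, which after Cre recombination tags ribosomes with GFP through the ribosomal protein Rpl10a. In translating ribosome affinity purification (TRAP), an antibody to GFP pulls down tagged ribosomes with the mRNA they carry. That RNA is called the positive fraction here. The input is part of the same cleared lysate, set aside before the pull-down. Each tissue had 3 input and 3 positive libraries, from replicates numbered 421, 953 and 960, which made 18 libraries. The positive libraries of choroid were the shallowest, with 2649095 to 4587921 counts, and brain inputs ran from 9596740 to 32064355 counts. Across genes, which are not independent replicates, log2 CPM (counts scaled to a common library total) of replicate inputs correlated at 0.928 to 0.966 in choroid and 0.993 to 0.994 in retina. Brain inputs 421 and 953 correlated at 0.994, and brain input 960 correlated with them at 0.908 and 0.910. Positive libraries correlated at 0.923 to 0.940 in choroid, 0.943 to 0.973 in retina and 0.983 to 0.9903 in brain.

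A value after a gene symbol is its log2 fold change with standard error, and CPM values are means with standard deviation over 3 libraries. Adjusted p values come from edgeR quasi-likelihood tests with Benjamini-Hochberg correction. They set a difference against the spread between the 3 replicates of a group, pooled over the groups of a fit and moderated across genes. Without the replicate block this spread includes what an input shares with its own positive library. A gene is called higher or lower where its adjusted p is under 0.05. Beside each gene list stand the number of called members out of those measured and the median log2 fold change. Where the counts adjusted over the list alone differed, they follow. Where none follow, they were the same.

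Endothelial transcripts were higher in the choroid positive fraction than in its input. The junction adhesion gene Pecam1 (3.88±0.26, adjusted p = 5.8e-05) had 45.7±11.8 CPM in input and 675±109.9 CPM in positive libraries (chromosome 11, 106654218 to 106715281, mm10). The tight junction claudin Cldn5 (4.34±0.31, adjusted p = 6.93e-05) had 58.8±20.9 CPM in input and 1191±93.5 CPM in positive libraries. Plvap (3.77±0.28, adjusted p = 8.02e-05), which builds the diaphragms of endothelial fenestrae, had 276±65 CPM in input and 3760±723 CPM in positive libraries (chromosome 8, 71497753 to 71511769, mm10). The adrenomedullin receptor partner Ramp3 (4.31±0.22), the adhesion gene Esam (4.02±0.25), Fam167b (4.66±0.30) and the transcription factor Tcf15 (4.22±0.39) also had some of the steepest increases. The angiopoietin receptor Tek (3.42±0.32) and the VE-cadherin gene Cdh5 (2.85±0.36) were higher as well. Every measured pan-endothelial gene was higher (27 of 27 higher, median 3.44). The list test gave camera adjusted p = 7.49e-19, and adjusted p = 0.284 with an estimated correlation. Every measured gene of fenestrated endothelium was higher too (8 of 8 higher, median 3.27), with the IGF binding protein Igfbp3 (3.75±0.22) and the lipid phosphatase Ppap2a (3.34±0.21) (now Plpp1). That list test gave camera adjusted p = 3.91e-07, and adjusted p = 0.285 with an estimated correlation.

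Transport and junction genes of the blood-brain and blood-retina barriers went both ways in choroid (4 higher and 8 lower of 22, median -0.39; camera adjusted p = 0.42). The efflux pump Abcg2 (3.00±0.31) was higher, while the organic anion transporter Slc22a8 (-2.49±0.23) and the lipoprotein receptor Lrp8 (-1.68±0.18) were lower. The glucose transporter Slc2a1 (-0.81±0.28, adjusted p = 0.0424) was lower, with 1070±41 CPM in input and 609±227 CPM in positive libraries. This call was lost without input 421 (adjusted p = 0.0659), input 953 (0.101), input 960 (0.0804), positive 953 (0.107) or positive 960 (0.105), with adjusted p from 0.00388 to 0.241 over its 20 alternatives. Endothelial Wnt/beta-catenin genes were also mixed (6 higher and 3 lower of 13, median 0.79), with Sox17 (3.14±0.33) and Lef1 (2.70±0.29) higher. Most arterial genes were higher (11 higher and 1 lower of 14, median 2.07), among them the Notch ligand Dll4 (3.86±0.21) and the gap junction gene Gja5 (3.78±0.38). The receptor Notch4 (3.51±0.37), of the Notch pathway list, was higher as well. Most genes of caveolae and lipid handling were higher (8 higher and 1 lower of 9, median 2.35), among them the capillary lipase anchor Gpihbp1 (3.96±0.25) and the fatty acid binding protein Fabp4 (3.68±0.52). All measured MHC class I genes were higher (9 of 9 higher, median 2.21), with H2-K1 (2.61±0.22) and H2-D1 (2.89±0.26), paralogs whose reads are hard to separate. Immediate early genes were higher (10 of 12 higher, 11 and 0 adjusted over the list alone, median 1.61), with Ier2 (2.82±0.21), Atf3 (2.36±0.20) and Jun (2.17±0.19). Their list test gave camera adjusted p = 4.82e-06, and adjusted p = 0.284 with an estimated correlation.

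Transcripts of leukocytes were also higher in the choroid positive fraction, while the erythroid and platelet lists were not called without the replicate block (erythroid: 0 higher and 0 lower of 6, median -0.91, camera adjusted p = 0.389; platelet: 1 of 3 higher, median 1.29, camera adjusted p = 0.325). All measured pan-leukocyte genes were higher (12 of 12 higher, median 2.30), among them the CD45 gene Ptprc (1.47±0.25). Macrophage genes (12 of 13 higher, median 2.48) included Lyz2 (3.22±0.31) and Mrc1 (2.42±0.18). As a list they gave camera adjusted p = 6.08e-07, and adjusted p = 0.284 with an estimated correlation. Mast cell genes (5 of 6 higher, median 3.17) included the proteases Mcpt4 (4.07±0.52), Tpsb2 (3.66±0.37), Cpa3 (2.48±0.32) and Cma1 (3.78±0.52). Microglia genes, many of which other macrophages express, were higher (10 of 13 higher, 11 and 0 adjusted over the list alone, median 2.82), with Cx3cr1 (2.13±0.34), C1qa (3.20±0.32) and Aif1 (3.48±0.32).

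Genes of the surrounding tissue were lower. The retinoid isomerase Rpe65 (-2.21±0.30, adjusted p = 0.000762) had 1801±415 CPM in input and 390.4±136 CPM in positive libraries, and Otx2 (-2.18±0.30) and Lrat (-2.22±0.31) were lower with the rest of the RPE list (11 of 11 lower, median -2.10). The list test gave camera adjusted p = 6.77e-06, and adjusted p = 0.316 with an estimated correlation. The pigment genes Tyr (-2.08±0.19) and Oca2 (-2.24±0.28) were lower with all measured melanocyte genes (9 of 9 lower, median -1.77). Fibroblast genes (9 of 11 lower, median -1.53) were lower with Col1a2 (-1.56±0.21) and Col6a1 (-2.23±0.32), and mural cell genes (1 higher and 8 lower of 14, 1 and 11 adjusted over the list alone, median -1.30) with Cspg4 (-1.32±0.24) and Tagln (-1.20±0.22). The integrin Itgb8 (-3.04±0.52), Capn6 (-2.95±0.30) and Plch1 (-2.92±0.24) had the lowest values of the named genes.

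Glial transcripts differed between the choroid libraries themselves. The myelin gene Mbp had 2998 CPM in input 421 against 97.2 and 156 CPM in inputs 953 and 960. The astrocyte filament gene Gfap had 950.4 against 62.5 and 55.1 CPM. Neither gene was called (Mbp (-1.77±1.49, adjusted p = 0.361) and Gfap (-1.38±1.30, adjusted p = 0.419)), nor was the neuronal Snap25 (-1.45±0.73, adjusted p = 0.138). With the replicate number as a block all 3 were lower: Mbp at -1.66 (adjusted p = 7.51e-06), Gfap at -1.32 (0.00023) and Snap25 at -1.54 (7.08e-05). They were lower also without both fractions of 421: Mbp at -1.54 (adjusted p = 0.0121), Gfap at -1.21 (0.0174) and Snap25 at -1.36 (0.002). With only 1 fraction of 421 left out the other stayed in its arm: without positive 421 Mbp had -4.62 (adjusted p = 0.0471), and without input 421 Snap25 had -1.89 (adjusted p = 0.0454). Snap25 was also called with all 18 libraries in one fit (-1.47, adjusted p = 0.0337). Adjusted p ran from 7.51e-06 to 0.585 over its 19 alternatives for Mbp, 0.00023 to 0.664 over its 19 alternatives for Gfap and 7.08e-05 to 0.354 over its 20 alternatives for Snap25. The rod list (1 of 18 lower, median -1.31) had a camera adjusted p of 0.0614, and 1.56e-06 with the block. The oligodendrocyte list had 0.215 and 0.0135, and the erythroid list 0.389 and 0.0196, each in the lower direction. With the block and an estimated correlation none of the 3 was called (adjusted p = 0.403, 0.413 and 0.439).

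Of 11718 genes tested in choroid, 2471 were higher and 2451 lower in the positive fraction, 1454 and 1717 of them by at least 2-fold. Without input 953 there were 1609 higher. Scaling by library size only moved the median of all genes from -0.03 to -0.26 and gave 1756 higher and 3340 lower. The balance between the directions therefore rests on the scaling.

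In retina, endothelial transcripts were rare in the input and much higher in the positive fraction. The claudin Cldn5 (6.74±0.17, adjusted p = 4.02e-07) had 4.59±0.0145 CPM in input and 491±79.9 CPM in positive libraries, and Cdh5 (6.98±0.36, adjusted p = 2.33e-06), Pecam1 (6.16±0.22, adjusted p = 5.71e-07) and Tek (6.58±0.31) were higher. Among the highest values were Ly6c2 (7.90±0.43) and its paralog Ly6c1 (7.18±0.22), surface proteins whose reads cannot be separated with certainty, and the GTPase Gimap6 (7.29±0.25). The endothelial transcription factors Erg (7.25±0.52), Sox17 (6.92±0.38) and Gata2 (6.89±0.31) and the adenylyl cyclase Adcy4 (7.34±0.32) followed. All but 1 of the pan-endothelial genes were higher (26 of 27 higher, median 6.10), and their list test gave camera adjusted p = 7.05e-26, and adjusted p = 0.284 with an estimated correlation. The exception was the VEGF receptor Kdr (0.19±0.23, adjusted p = 0.555), with 129±15.2 CPM in input and 147±56.5 CPM in positive libraries.

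Barrier genes were higher as a group in retina (19 of 23 higher, 20 and 0 adjusted over the list alone, median 3.50). Their list test gave camera adjusted p = 1.79e-12, and adjusted p = 0.285 with an estimated correlation. The glucose transporter Slc2a1 (2.70±0.18, adjusted p = 1.01e-05) had 218±1.83 CPM in input and 1413±331 CPM in positive libraries. The drug efflux pump Abcb1a (6.76±0.42), the organic anion transporter Slco1a4 (6.13±0.32) and the tricellular junction gene Lsr (4.34±0.18) were higher, as were the lipid transporter Mfsd2a (5.04±0.48) and the amino acid transporter Slc7a5 (3.39±0.27). Wnt/beta-catenin genes of barrier endothelium were higher (12 of 13 higher, median 2.41), with Foxf2 (6.37±0.33), Foxq1 (5.98±0.33) and Lef1 (5.88±0.43). As a list they gave camera adjusted p = 1.93e-09, and adjusted p = 0.284 with an estimated correlation. Genes of fenestrated endothelium were higher as a list (5 higher and 1 lower of 7, median 0.72), with camera adjusted p = 0.00937, and adjusted p = 0.284 with an estimated correlation. Igfbp3 (4.78±0.32) and Nrp1 (2.39±0.20) were higher, and Plvap (0.32±0.20, adjusted p = 0.248) was not called. Arterial genes (13 of 14 higher, median 4.80) were higher with Sema3g (5.77±0.33) and Bmx (6.10±0.38), and so were venous genes (9 of 10 higher, median 3.23). Basement membrane genes (11 of 12 higher, median 2.33) included the laminin Lama4 (4.84±0.44) and the nidogen Nid1 (4.15±0.50).

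Immune genes were higher in the retina positive fraction. MHC class I genes (9 of 9 higher, median 2.63) included B2m (3.78±0.14) and H2-K1 (2.63±0.13), and interferon response genes (9 of 10 higher, median 2.37) included Ifitm3 (4.76±0.21), Bst2 (3.75±0.29) and Rsad2 (3.58±0.27). All measured microglia genes were higher (12 of 12 higher, median 4.05), with Tyrobp (5.08±0.38), C1qa (4.21±0.50), Siglech (4.30±0.46) and Cx3cr1 (3.66±0.46). All measured pan-leukocyte genes were higher too (5 of 5 higher, median 4.33). Only these 5 were listed in retina, and the listing rule given above may have raised their share. The microglia list test gave camera adjusted p = 2.06e-07, and adjusted p = 0.332 with an estimated correlation. Cx3cr1 had 23.4 CPM in positive 421 against 86.6 and 94.1 CPM in positives 953 and 960. With the replicate block the erythroid list had a camera adjusted p of 0.0409 (0.0863 without) and the macrophage list 0.0338 (0.088 without), both in the higher direction. Neither was called with the block and an estimated correlation (adjusted p = 0.403 and 0.439).

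Lists of neuron, photoreceptor, Müller glia and astrocyte genes had medians of -0.78 to -0.19 in retina, with some members much lower. Neuron genes were lower as a group (9 of 15 lower, 0 and 12 adjusted over the list alone, median -0.56), and their list test gave camera adjusted p = 4.98e-05, and adjusted p = 0.339 with an estimated correlation. Cone genes (1 higher and 7 lower of 12, 1 and 8 adjusted over the list alone, median -0.71) were lower with Pde6h (-2.25±0.19) and Opn1mw (-1.90±0.19). Most Müller glia genes were lower (1 higher and 7 lower of 10, 1 and 8 adjusted over the list alone, median -0.78), while Vim (1.44±0.12), an intermediate filament gene that endothelium also expresses, was higher. The RPE list was also lower in retina (camera adjusted p = 0.00743, and adjusted p = 0.317 with an estimated correlation). Of its genes, Rgr (-2.03±0.25) was lower, and the thyroid hormone carrier Ttr (-2.38±0.20) had the lowest value of the named genes. Few rod genes were called (4 of 18 lower, median -0.34), and as a list they gave camera adjusted p = 0.00553, and adjusted p = 0.526 with an estimated correlation, in the lower direction. The markers Snap25 (-0.35±0.21, adjusted p = 0.226), Mbp (-0.39±0.17, adjusted p = 0.104) and Gfap (0.30±0.29, adjusted p = 0.446) were not called. Without positive 960 Snap25 had -0.55 (adjusted p = 0.0192) and Mbp -0.53 (0.0191). The pericyte marker Rgs5 had 292 CPM in positive 421 against 25.5 and 8.71 CPM in positives 953 and 960, and few mural cell genes were called (2 of 5 higher, 2 and 1 adjusted over the list alone, median 1.12).

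Of 12369 genes tested in retina, 2226 were higher and 1696 lower in the positive fraction. By at least 2-fold, 1074 were higher and 113 lower. Single libraries moved these counts: they were 1355 and 710 without input 421, 1292 and 659 without input 953, and 1314 and 586 without input 960. The lower count was 856 without positive 953 and 2653 without positive 960.

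In brain, the positive fraction held more of every measured pan-endothelial transcript (27 of 27 higher, median 5.18). Their list test gave camera adjusted p = 4.74e-20, and adjusted p = 0.284 with an estimated correlation. Pecam1 (5.85±0.27, adjusted p = 4.11e-05) had 12.6±2.39 CPM in input and 731±146 CPM in positive libraries. The glucose transporter Slc2a1 (4.48±0.23, adjusted p = 4.12e-05), the main route of glucose across the blood-brain barrier, had 116±5.12 CPM in input and 2594±632 CPM in positive libraries. The GTPase Gimap5 (6.24±0.40), the transcription factor Erg (6.18±0.38), the riboflavin transporter Slc52a3 (6.07±0.21) and the adhesion gene Icam2 (6.05±0.30) had some of the highest values, with the kinase Bmx (6.04±0.26) and the guidance receptor Robo4 (5.96±0.32). Cdh5 (5.39±0.43), Tek (5.58±0.33) and Cldn5 (5.14±0.60) were higher as well. Barrier genes were nearly all higher (21 of 23 higher, median 3.92), with Abcb1a (5.30±0.34), Slco1a4 (5.07±0.26), Abcg2 (4.46±0.24) and Mfsd2a (2.77±0.22). As a list they gave camera adjusted p = 2.57e-11, and adjusted p = 0.284 with an estimated correlation. All measured Wnt/beta-catenin genes were higher (14 of 14 higher, median 3.74), with Foxf2 (5.55±0.24), the Wnt deacylase Notum (4.44±0.23) and Lef1 (3.94±0.22). Plvap (0.29±0.24, adjusted p = 0.377) was not called in brain, while Igfbp3 (1.76±0.21), also on the fenestrated list (6 higher and 1 lower of 9, median 1.76), was higher. That list gave camera adjusted p = 0.009, and adjusted p = 0.285 with an estimated correlation.

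Microglia, macrophage, pan-leukocyte and MHC class I genes were among the most uniform groups in brain. The erythroid, platelet and neutrophil lists were not called without the replicate block (erythroid: 0 higher and 0 lower of 6, median -0.80, camera adjusted p = 0.452; platelet: 2 of 4 higher, median 2.22, camera adjusted p = 0.224; neutrophil: 1 of 4 higher, median 1.60, camera adjusted p = 0.142). All measured microglia genes were higher (18 of 18 higher, median 3.65), with the complement gene C1qb (4.05±0.20), Tmem119 (3.74±0.21) and Fcrls (3.78±0.22). Their list test gave camera adjusted p = 1.68e-11, and adjusted p = 0.284 with an estimated correlation. Cx3cr1 (3.15±0.28, adjusted p = 0.000231) had 65.4±21.4 CPM in input and 581±95.9 CPM in positive libraries. All measured macrophage genes were higher (15 of 15 higher, median 3.47), with Mrc1 (3.47±0.19) and F13a1 (3.59±0.27). Pan-leukocyte genes were too (11 of 12 higher, 12 and 0 adjusted over the list alone, median 3.62), with Ptprc (2.24±0.19). MHC class I genes (10 of 10 higher, median 3.24) included H2-D1 (3.41±0.22) and Psmb9 (4.36±0.26), and interferon response genes (13 of 13 higher, median 3.23) included Oas1a (4.26±0.38) and Ifitm3 (4.53±0.42).

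Genes of the brain parenchyma were lower. Oligodendrocyte lineage genes (12 of 13 lower, 0 and 13 adjusted over the list alone, median -1.86) included Gpr17 (-1.98±0.27) and Opalin (-2.33±0.34). Their list test gave camera adjusted p = 3.31e-06, and adjusted p = 0.333 with an estimated correlation. Gpr37 (-2.36±0.27), outside that list, was lower too. The myelin gene Mbp (-1.63±0.33, adjusted p = 0.00857) had 2223±117 CPM in input and 717±348 CPM in positive libraries. Astrocyte genes were lower (8 of 11 lower, 0 and 11 adjusted over the list alone, median -1.01), and so were neuron genes (8 of 15 lower, 0 and 12 adjusted over the list alone, median -0.74), with Snap25 (-0.74±0.15, adjusted p = 0.00902). The calls of Mbp and Snap25 were lost with all 18 libraries in one fit (adjusted p = 0.178 and 0.143), without replicate 421 (0.0782 and 0.185) and without replicate 953 (0.117 and 0.158). Adjusted p ran from 5.22e-06 to 0.178 over its 20 alternatives for Mbp and from 1.47e-05 to 0.185 over its 19 alternatives for Snap25. Choroid plexus genes (6 of 6 lower, median -1.46) were lower with Kl (-1.71±0.18). The fibroblast list was lower too (6 of 8 lower, 0 and 7 adjusted over the list alone, median -1.34). It included Dcn (-1.84±0.31) and Pdgfra (-2.21±0.30), which in brain is not particular to fibroblasts. Gfap (-0.75±0.21, adjusted p = 0.0282) was lower with all 6 libraries. It was not called without input 421 (adjusted p = 0.0919), input 953 (0.0919), positive 421 (0.117), positive 953 (0.0858) or positive 960 (0.0548), or with the replicate block (0.0801), with adjusted p from 1.57e-05 to 0.428 over its 20 alternatives. With the block the neutrophil list had a camera adjusted p of 0.0142 (0.142 without) in the higher direction. The nuclear long noncoding RNA list had 0.0411 (0.0768 without) in the lower direction. With the block and an estimated correlation these lists were not called (adjusted p = 0.43 and 0.413).

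Of 12919 genes tested in brain, 2744 were higher and 2359 lower in the positive fraction, 1958 and 991 of them by at least 2-fold. Without brain input 960, the shallowest brain library, 4670 genes were higher and 4642 lower. The lower count was 1490 without input 421, 1488 without input 953, 1005 without positive 421 and 1096 without positive 953.

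**Figure D1:**
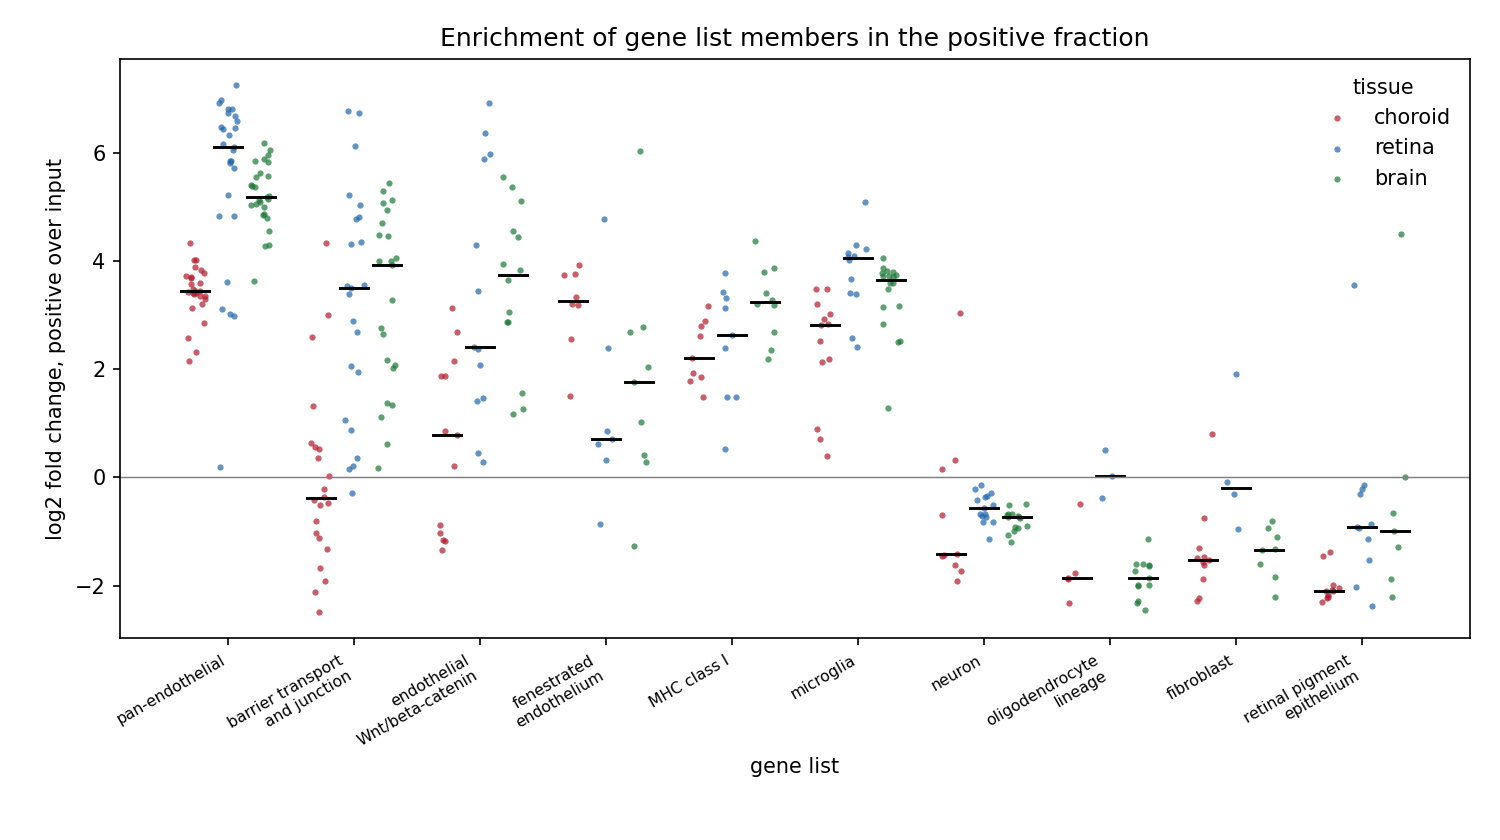
Log2 fold change of positive over input for members of 10 gene lists in each tissue, with the median as a black line. The pan-endothelial medians were 3.44 in choroid, 6.10 in retina and 5.18 in brain, and the barrier medians -0.39, 3.50 and 3.92.

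**Figure D2:**
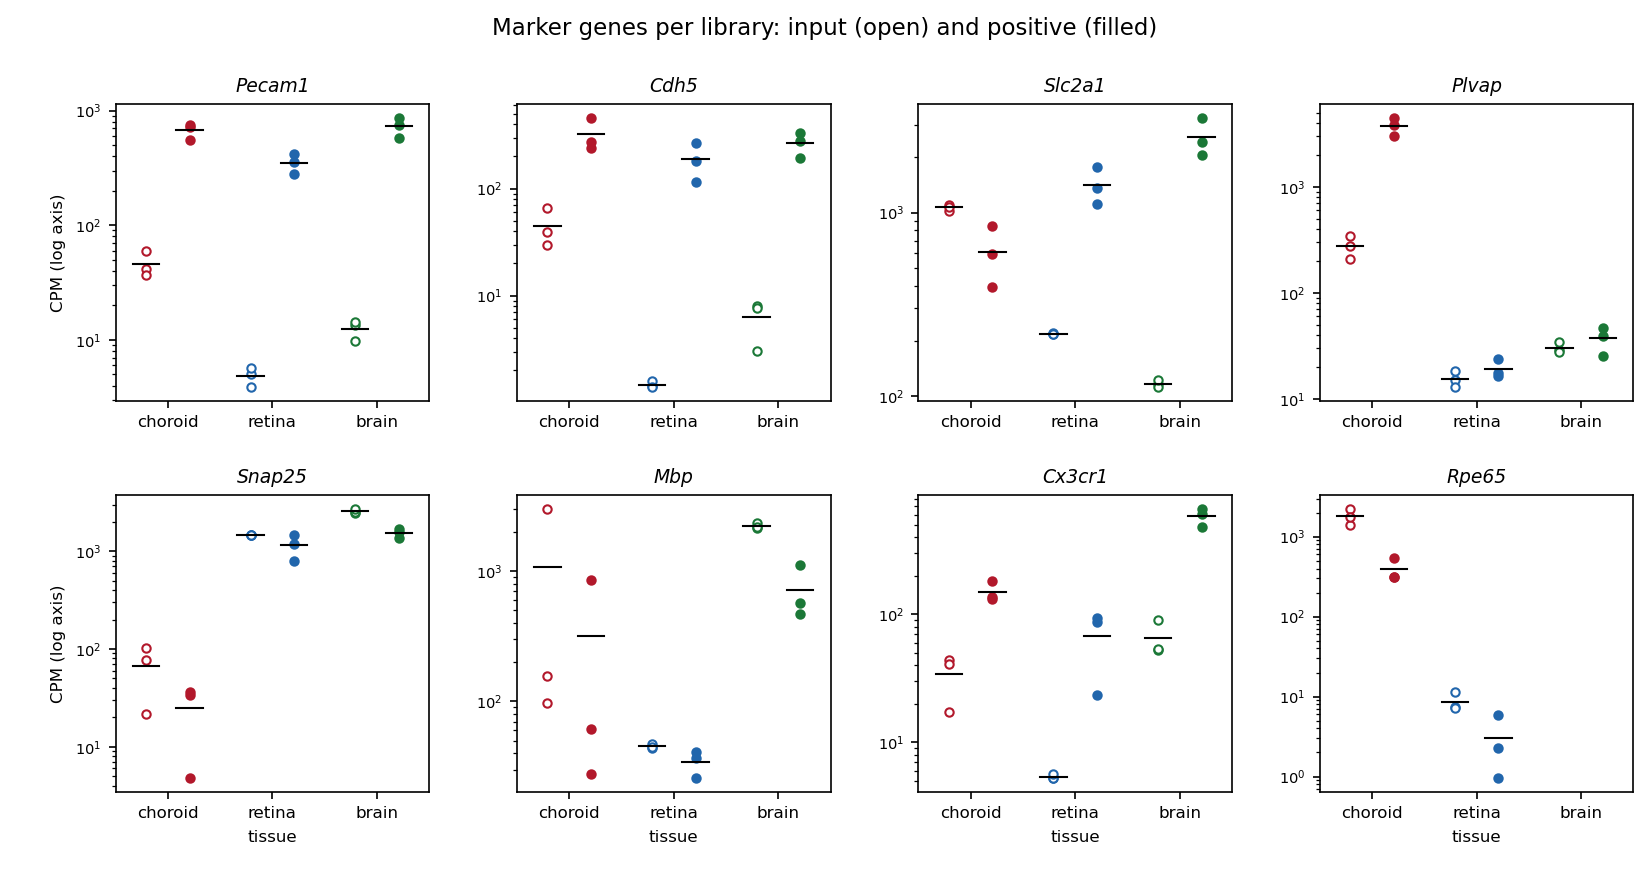
CPM per library on a log axis for Pecam1, Cdh5, Slc2a1, Plvap, Snap25, Mbp, Cx3cr1 and Rpe65, inputs open and positive fractions filled, 3 libraries each. Mbp had 2998 CPM in choroid input 421, and Rpe65 was not listed in the brain table.

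Genes called higher by at least 2-fold are termed enriched. Of 10505 genes measured in all 3 tissues, 447 were enriched in every tissue, against 13.9 if the 3 sets were independent. The sets held 1162 genes in choroid, 975 in retina and 1357 in brain. Retina and brain alone shared 277 (112 with independence), choroid and brain alone 172 (136), and choroid and retina alone 44 (93.9). These counts leave out the 447, so a count under its expectation does not mean that 2 tissues shared less than with independence. With the 447 counted in, retina and brain shared 724 genes, choroid and brain 619, and choroid and retina 491. The pan-endothelial genes Pecam1, Cdh5, Tek, Esam and Cldn5 were enriched in all 3 tissues, as were Cx3cr1 and C1qa of the microglia list. The 3 comparisons use different inputs, so that a ratio depends on the other cells of each tissue.

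Enrichment in retina and brain was compared through the difference of their log2 ratios. The VEGF receptor Kdr (-4.80±0.45, adjusted p = 6.53e-06) was less enriched in retina (0.15 in retina and 4.94 in brain). The caveolar coat gene Cav1 (-3.77±0.29, adjusted p = 1.12e-06) and the membrane glycoprotein gene Prom1 (-5.12±0.56, adjusted p = 2.74e-05) were less enriched there too, as were Gngt2 (-4.94±0.56), the sialyltransferase St6galnac2 (-3.98±0.29) and Rad54b (-3.95±0.32). More enriched in retina were the membrane protein Mal (5.55±0.53, adjusted p = 7.05e-06), with ratios of 6.49 in retina and 0.94 in brain, the lipid carrier Apod (5.27±0.54, adjusted p = 1.4e-05) and the growth factor receptor Fgfr3 (4.76±0.54). The endothelial genes Cd34 (2.94±0.31), Thbd (2.70±0.38) (thrombomodulin) and Igfbp3 (3.16±0.37) were as well. Positive-fraction levels did not follow every ratio: Mal had 346±59.4 CPM in retina and 564±65.3 CPM in brain. Scaled within each tissue, Kdr had 110 to 212 CPM in retina positives and 116 to 187 CPM in brain positives. Its inputs differed, with 113 to 144 CPM in retina and 2.93 to 5.37 CPM in brain. Immediate early genes were less enriched in retina (5 of 12 lower, 0 and 6 adjusted over the list alone, median -0.59), with Btg2 (-2.27±0.25), and their list test gave camera adjusted p = 0.0012, and adjusted p = 0.282 with an estimated correlation. MHC class I genes gave camera adjusted p = 0.00171, and adjusted p = 0.441 with an estimated correlation, also in the lower direction (2 of 9 lower, 0 and 4 adjusted over the list alone, median -0.87). Tip cell genes were more enriched in retina (4 of 6 higher, median 0.96), or 2 of them with library size only, and gave camera adjusted p = 0.00245, and adjusted p = 0.155 with an estimated correlation. Neither the pan-endothelial list (7 higher and 5 lower of 27, 11 and 5 adjusted over the list alone, median 0.94; camera adjusted p = 0.265) nor the barrier list (3 higher and 2 lower of 22, 4 and 3 adjusted over the list alone, median -0.24; camera adjusted p = 0.303) was called. Pecam1 (0.46±0.33, adjusted p = 0.373) and Plvap (0.17±0.35, adjusted p = 0.774) were not called, and Slc2a1 (-1.64±0.34, adjusted p = 0.0052) was less enriched in retina.

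Of 10505 genes, 875 were more and 522 less enriched in retina than in brain, 618 and 355 by at least 2-fold. The median of all genes was 0.20, and this offset depended on the scaling. With library size only the median was 0.12 and the counts were 631 and 574, and with only the 2 tissues the median was -0.028. TMM scales each library to 1 reference library, which was choroid input 421 with all 18 libraries. With brain input 421 as the reference and all 18 libraries kept, the scaling shifted this difference by -0.2052 for every gene. The median was then -0.0072, and 447 genes were more and 885 less enriched in retina. Over the 18 possible references the shift ran from -0.3295 to 0.1015. Brain input 421 was also the reference without choroid input 421 or 960, without any 1 choroid positive library (median -0.0071 to -0.0072), without brain input 960 (-0.0799) and without replicate 960 (-0.0904). Single values are to be read relative to these offsets, and which direction held more genes rests on the scaling. The tests of the reference were chosen after the data were seen. Libraries of every tissue moved these counts. Without brain input 960, 1571 were less enriched, and without brain positive 421, 438 were more. Without brain positive 953 the counts were 429 and 319. They were 483 and 891 without choroid input 421, 428 and 858 without choroid input 960, and 564 and 992 without both choroid fractions of 421. Without choroid positives 421, 953 or 960 they were 485 and 967, 468 and 918, or 473 and 930. The number more enriched was 485, 445 or 520 without retina inputs 421, 953 or 960, and 547 without retina positive 953.

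Barrier genes were less enriched in choroid than in brain. The glucose transporter Slc2a1 (-5.12±0.36, adjusted p = 1.08e-07) had ratios of -0.83 in choroid and 4.29 in brain. Part of this difference lay in the inputs, with 1026 to 1106 CPM in choroid and 111 to 122 CPM in brain, scaled within each tissue. The positive libraries had 391 to 843 CPM and 2061 to 3291 CPM. The thyroid hormone transporter Slco1c1 (-6.63±0.62, adjusted p = 1.53e-06), Slc22a8 (-6.31±0.47, adjusted p = 1.96e-07), Slco1a4 (-5.36±0.43) and Slc7a5 (-4.86±0.45) were less enriched there too. So was the retinol receptor Stra6 (-6.42±0.57), which is on the RPE list and not the barrier list. No barrier gene was more enriched in choroid (19 of 22 lower, median -2.89), and the list test gave camera adjusted p = 5.87e-15, and adjusted p = 0.155 with an estimated correlation. Wnt/beta-catenin genes were less enriched in choroid (1 higher and 10 lower of 12, 1 and 11 adjusted over the list alone, median -2.58), with the Wnt inhibitor Apcdd1 (-5.51±0.70), the receptor Fzd4 (-4.20±0.58) and Foxf2 (-3.50±0.34). Venous genes (6 of 8 lower, 0 and 7 adjusted over the list alone, median -2.17) and interferon response genes (8 of 10 lower, 0 and 9 adjusted over the list alone, median -2.68) were less enriched too, the latter with Irf7 (-4.12±0.54), Ifit3 (-2.88±0.39) and Ifitm3 (-2.91±0.44). Genes of fenestrated endothelium were more enriched in choroid (6 of 7 higher, median 2.49), and gave camera adjusted p = 9.84e-07, and adjusted p = 0.155 with an estimated correlation. Among them were Plvap (3.65±0.35, adjusted p = 1.88e-06), with ratios of 3.75 in choroid and 0.10 in brain, Ppap2a (2.49±0.20, adjusted p = 3.49e-07) and Cd24a (2.93±0.32). Ramp3 (4.37±0.32, adjusted p = 1.79e-07), the fatty acid binding protein Fabp5 (4.09±0.31), the water channel Aqp1 (4.02±0.37) and the small GTPase Rnd1 (4.04±0.37) were also more enriched there. Pan-endothelial genes were less enriched in choroid (22 of 27 lower, 0 and 24 adjusted over the list alone, median -1.67), with Pecam1 (-1.79±0.32, adjusted p = 0.000708) and Ramp2 (-2.22±0.30). Pecam1 had 36.6 to 59.1 CPM in choroid inputs and 9.86 to 14.4 CPM in brain inputs, scaled within each tissue. Its positive libraries had 550 to 755 CPM and 575 to 864 CPM, so its difference lay mostly in the inputs. Cldn5 (-0.63±0.53, adjusted p = 0.405) was not called, and without brain input 960 it had -1.69 (adjusted p = 0.00086, in a range of 0.00086 to 0.906 over its 32 alternatives). Immediate early genes went both ways (6 higher and 3 lower of 12, median 0.78), with Fos (2.10±0.32) and Junb (1.71±0.31) more enriched in choroid.

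Of 10505 genes, 1286 were more and 1296 less enriched in choroid than in brain, 746 and 1018 by at least 2-fold. The median of all genes was 0.08, -0.0936 with brain input 421 as the reference (812 more and 1736 less enriched) and -0.137 without choroid positive 421. With library size only it was -0.26 and the counts were 547 and 2196. Without brain input 960, 2077 were less enriched. The number more enriched was 812 without choroid input 421 and also without both choroid fractions of 421, 709 without choroid input 960, 622 without choroid positive 953 and 754 without choroid positive 960.

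Against retina, choroid was again less enriched for barrier genes (1 higher and 19 lower of 22, median -3.42), and the list test gave camera adjusted p = 1.86e-11, and adjusted p = 0.211 with an estimated correlation. Slc2a1 (-3.48±0.35, adjusted p = 2.92e-06) had ratios of -0.83 in choroid and 2.65 in retina, and Mfsd2a (-6.33±0.53, adjusted p = 6.22e-07) and Slco1a4 (-6.57±0.44, adjusted p = 1.7e-07) were less enriched too. Part of the Slc2a1 difference again lay in the inputs, with 1026 to 1106 CPM in choroid and 216 to 220 CPM in retina. The caspase Casp12 (-7.27±0.70), the phospholipid transfer protein Pltp (-6.81±0.51) and the semaphorin Sema3c (-6.59±0.49) were among the lowest values. Wnt/beta-catenin genes were less enriched in choroid (10 of 12 lower, 1 and 10 adjusted over the list alone, median -2.94), with Tnfrsf19 (-5.42±0.45), Foxf2 (-4.46±0.38) and Foxq1 (-4.09±0.51). Plvap (3.47±0.36, adjusted p = 3.8e-06) was more enriched in choroid, with ratios of 3.75 in choroid and 0.27 in retina, and Kdr (3.52±0.43, adjusted p = 2.7e-05) with 3.67 in choroid and 0.15 in retina. Ramp3 (4.56±0.32, adjusted p = 2.18e-07), Fabp5 (3.73±0.31), Ppap2a (2.74±0.20) and Cd24a (2.35±0.33) were more enriched too. The fenestrated list (5 higher and 1 lower of 7, median 2.41) gave camera adjusted p = 3.46e-05, and adjusted p = 0.211 with an estimated correlation. Most pan-endothelial genes were less enriched in choroid (1 higher and 22 lower of 27, median -2.67), with Cdh5 (-4.11±0.57), Tek (-3.13±0.47), Pecam1 (-2.26±0.33) and Cd34 (-3.83±0.31), and Kdr was the exception. The inputs differed here too: Cdh5 had 29.9 to 66.4 CPM in choroid and 1.39 to 1.59 CPM in retina, scaled within each tissue. Its positive libraries had 242 to 459 CPM and 116 to 268 CPM, so its lower ratio did not reflect a lower level in the choroid positives. In the direct comparison of positive fractions below, most pan-endothelial genes were higher in choroid. Immediate early genes were more enriched in choroid (10 of 12 higher, median 1.44), or 7 of them with library size only, with Jun (1.98±0.25), Ier2 (2.16±0.37) and Btg2 (1.45±0.25). As a list they gave camera adjusted p = 4.94e-06, and adjusted p = 0.155 with an estimated correlation.

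Of 10505 genes, 1141 were more and 1887 less enriched in choroid than in retina, 583 and 1524 by at least 2-fold. The median of all genes was -0.07. With library size only it was -0.33 and the counts were 580 and 2683. With the size factors of DESeq2 the median was -0.10, and without brain input 960 there were 1863 more enriched.

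The positive fractions were also compared directly between tissues. This leaves out the inputs and so includes whatever other RNA each pull-down held. Genes also enriched over input in the tissue in which they were higher were counted apart. These held blood-lineage genes as well as endothelial ones, since both were enriched. Most pan-endothelial transcripts were lower in retina than in brain (20 of 27 lower, median -1.24), with Ramp2 (-2.07±0.20), Sox18 (-2.08±0.21) and Esam (-1.73±0.19). Cldn5 (-1.45±0.20, adjusted p = 4.61e-05) had 521±82.6 CPM in retina and 1427±189.7 CPM in brain. Barrier genes went both ways (4 higher and 10 lower of 22, 4 and 12 adjusted over the list alone, median -0.73). The monocarboxylate transporter Slc16a1 (1.27±0.25) and the transferrin receptor Tfrc (1.01±0.21) were higher in retina, and the junction gene Lsr (-1.65±0.17) and the anion transporter Slc22a8 (-2.58±0.32) lower. Microglia genes were lower in retina (10 of 10 lower, median -3.11), with C1qb (-3.46±0.49, adjusted p = 6.33e-05), C1qa (-3.18±0.43) and Cx3cr1 (-3.01±0.40). MHC class I genes (9 of 9 lower, median -1.58) and ribosomal protein genes (72 of 73 lower, median -1.01) were lower as well. Higher in retina were the nuclear noncoding RNA Xist (5.53±0.48), the lipase Pnpla3 (4.34±0.23), the collagen Col20a1 (4.38±0.40), the Notch ligand Jag1 (2.69±0.24) and the mural cell gene Vtn (4.33±0.50). Of 10505 genes, 3367 were higher and 3254 lower in retina, 1935 and 1581 by at least 2-fold, and 115 and 882 were also enriched over input in the tissue in which they were higher.

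Between the positive fractions of choroid and brain, the fenestral gene Plvap (6.74±0.33, adjusted p = 1.45e-08) had 3994±793 CPM in choroid and 37.4±10.9 CPM in brain. All measured genes of fenestrated endothelium were higher in choroid (7 of 7 higher, median 3.78), with Igfbp3 (5.58±0.30) and Cd24a (5.19±0.25). The fatty acid receptor Cd36 (5.76±0.26), of the capillary and caveolae lists, was higher too. Most barrier genes were lower in choroid (2 higher and 17 lower of 22, median -1.85): Slc2a1 (-2.01±0.31, adjusted p = 0.000148) had 647±245 CPM in choroid and 2604±621 CPM in brain, and Slco1c1 (-4.80±0.49), Mfsd2a (-4.10±0.43), Slc7a5 (-3.67±0.32), Ocln (-3.55±0.35) and Lsr (-2.69±0.18) were lower. Wnt/beta-catenin genes were mostly lower too (1 higher and 9 lower of 12, median -1.46), with Apcdd1 (-4.99±0.35). Pan-endothelial genes went both ways (11 higher and 3 lower of 27, median 0.41). Pecam1 (-0.04±0.22, adjusted p = 0.911), Cdh5 (0.36±0.32, adjusted p = 0.38), Tek (0.33±0.28, adjusted p = 0.352) and Cldn5 (-0.17±0.19, adjusted p = 0.488) were not called, and Kdr (3.19±0.31) and Emcn (2.35±0.24) were higher in choroid. The melanosome and macrophage glycoprotein Gpnmb (9.78±0.51) and the lysozyme Lyz2 (5.47±0.43) were higher in choroid, as were the RPE genes Rlbp1 (5.91±0.39) and Rdh5 (7.21±0.42) (6 of 7 higher, median 3.98). Neuron genes were lower (10 of 10 lower, median -4.80), with Snap25 (-5.90±0.57). Of 10505 genes, 2424 were higher and 2495 lower in choroid, 1010 and 1495 by at least 2-fold, and 638 and 204 were also enriched over input in the tissue in which they were higher. With library size only the median of all genes was -0.14 and the counts were 1711 and 3086.

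Between choroid and retina, Plvap (7.61±0.34, adjusted p = 7.48e-09) had 3994±793 CPM in choroid and 20.4±4.18 CPM in retina. All measured genes of fenestrated endothelium (7 of 7 higher, median 4.72) and of caveolae (7 of 7 higher, median 1.79) were higher in choroid, with Igfbp3 (6.10±0.31), Fabp5 (6.23±0.29), Cd36 (6.18±0.28) and Ppap2a (4.72±0.20). Pan-endothelial genes were mostly higher in choroid (22 of 27 higher, median 1.91), with Pecam1 (0.94±0.22, adjusted p = 0.00184), Cldn5 (1.28±0.20) and Emcn (4.29±0.26). Barrier genes were mostly lower (3 higher and 14 lower of 22, median -1.31), with Slc7a5 (-2.98±0.31), Ocln (-2.54±0.35), Tfrc (-2.30±0.23) and Slc2a1 (-1.21±0.30, adjusted p = 0.00267). MHC class I genes were higher in choroid (9 of 9 higher, median 3.17), with H2-D1 (3.73±0.22), as were the macrophage genes Lyz2 (7.52±0.47) and Cd74 (6.17±0.46). Ribosomal protein genes were higher too (72 of 73 higher, median 1.34). Most neuron genes were lower (1 higher and 9 lower of 10, median -4.09), with Snap25 (-5.57±0.56), and so were Pnpla3 (-7.25±0.33), the noncoding RNA Snhg11 (-6.67±0.40) and the cytoskeletal linker Dst (-4.97±0.42). Of 10505 genes, 3461 were higher and 4105 lower in choroid, 2207 and 2844 by at least 2-fold, and 947 and 151 were also enriched over input in the tissue in which they were higher. The median of all genes was -0.11, and with library size only -0.32.

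**Figure D3:**
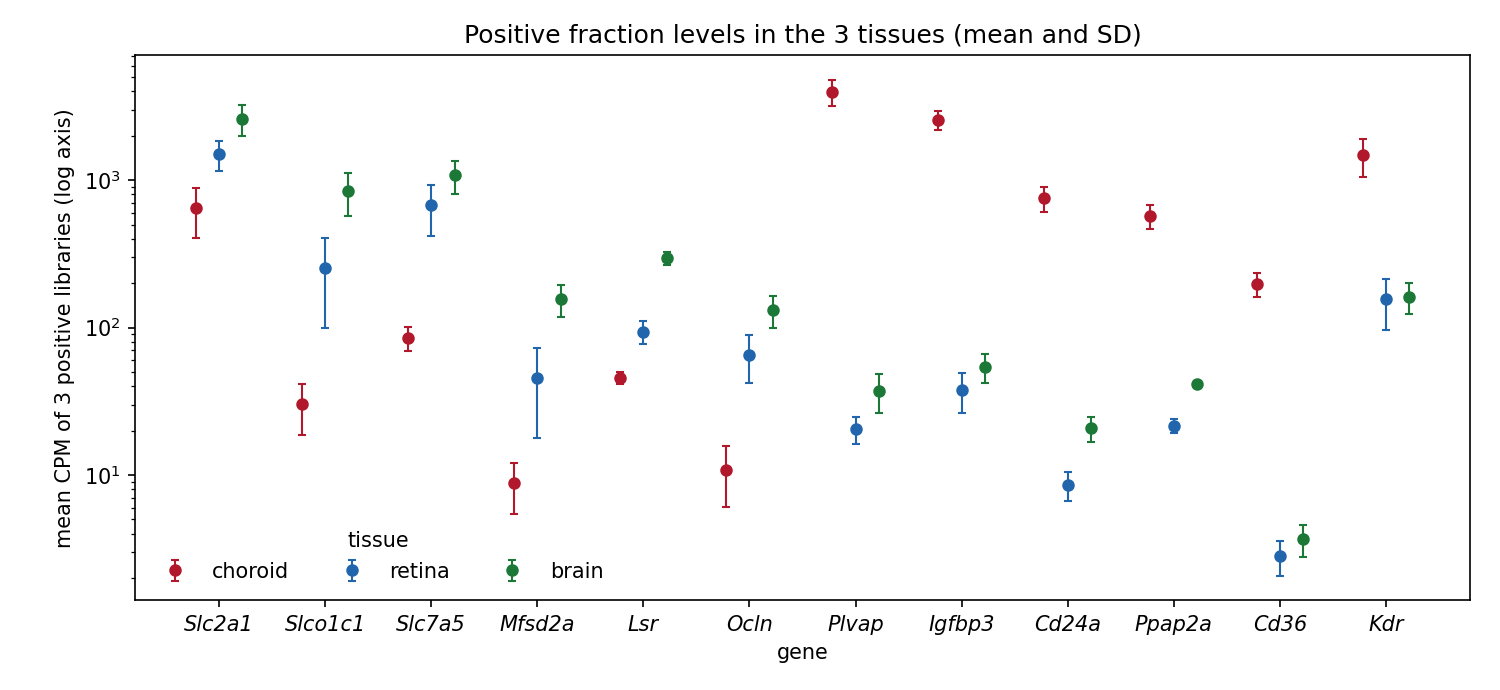
Mean CPM of 3 positive libraries per tissue, with standard deviation and on a log axis, for 6 barrier genes (Slc2a1, Slco1c1, Slc7a5, Mfsd2a, Lsr, Ocln) and 6 others (Plvap, Igfbp3, Cd24a, Ppap2a, Cd36, Kdr). Plvap had 3994±793 CPM in choroid, 20.4±4.18 in retina and 37.4±10.9 in brain.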

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

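For the effects below, the test of the difference between tissues was fixed before the data were examined. The tests of the 3 patterns that follow were chosen after the pattern was seen, and for the carry-over, other-tissue, shared-homogenate and all 3 microglial explanations also after the deciding value was seen.

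Enrichment differed between tissues by the test of the difference itself (edgeR quasi-likelihood, Benjamini-Hochberg over 10505 genes). Between retina and brain, 875 genes were more and 522 less enriched in retina. Of the named genes, the lipid raft protein Mal (5.55±0.53) and the lipid carrier Apod (5.27±0.54) were more enriched there, and the VEGF receptor Kdr (-4.80±0.45), the caveolar Cav1 (-3.77±0.29) and the glucose transporter Slc2a1 (-1.64±0.34) less. Positive-fraction levels did not follow the ratios of Mal and Kdr, as given above. The number of genes more enriched ran from 25 without replicate 953 to 1088 without replicate 960, and the number less enriched from 47 to 1661 in the same fits. Which direction held more genes rested on the reference library of the scaling, a test chosen after the data were seen: with brain input 421 in place of choroid input 421 the counts were 447 and 885. Slc2a1 was not called without replicate 953 (adjusted p = 0.198, in a range of 3.96e-05 to 0.198 over its 32 alternatives).

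Between choroid and brain, 1286 genes were more and 1296 less enriched in choroid. Those less enriched included the barrier transporters Slco1c1 (-6.63±0.62), Slc22a8 (-6.31±0.47) and Slc2a1 (-5.12±0.36), and those more enriched Ramp3 (4.37±0.32) and the fenestrated endothelium genes Plvap (3.65±0.35) and Ppap2a (2.49±0.20). Without replicate 953 the counts were 199 and 399.

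Between choroid and retina, 1141 genes were more and 1887 less enriched in choroid. Slco1a4 (-6.57±0.44), Mfsd2a (-6.33±0.53) and Slc2a1 (-3.48±0.35) were less enriched there, and Ramp3 (4.56±0.32), Plvap (3.47±0.36) and Kdr (3.52±0.43) more. In both comparisons with choroid, part of the Slc2a1 difference lay in its higher level in the choroid inputs, as given above. Without replicate 953 the counts were 144 and 480.

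Myelin and astrocyte transcripts stood out in both choroid fractions of replicate 421, where Mbp had 2998 CPM in the input against 97.2 and 156 CPM in the other inputs. Brain or retina tissue carried over is argued against by the neuron list, whose median lay at -0.347 (log2) against the other choroid inputs, and a library of another tissue under a choroid label by the RPE list, at -0.655, far above the -3 that this would need. Optic nerve tissue in the sample stays open. The test took 95 genes in no fixed list that were called lower in the brain positive fraction, at a log2 fold change of -1.5 or less. They lay 0.453 above all genes in this input, between the 0.2 that would exclude it and the 0.5 that would fit it. The set was not chosen by cell type, so its value is not one of glial genes alone. An optic nerve could bring glial genes without neuronal nuclei, but no marker of it alone was measured. No biological explanation was tested, since the labels give none for this replicate.

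Brain input 960 correlated with the other brain inputs at 0.908 and 0.910, against 0.994 between those. Depth is argued against, since inputs 421 and 953 thinned to its total still correlated at 0.9943 with each other unthinned. A transcript length trend was strong (Spearman correlation -0.55 against 0.522 and 0.525 in inputs 421 and 953, across genes, each as the deviation from the mean of its group, so that the signs are not independent). Over the 12421 genes with a known transcript length, its removal raised the mean correlation with the other inputs only from 0.912 to 0.9407, so it is not the whole cause. The trend was not particular to this library: it was -0.502 and -0.31 in the choroid input and positive of 960, and 0.424 and 0.398 in those of choroid 421. RNA broken down in the shared homogenate is argued against by brain positive 960, where the trend was 0.028. A step between the lysate and the sequencing of this input stays open and was not tested, and no biological explanation was tested.

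Microglial and leukocyte transcripts were higher in the brain positive fraction, with Cx3cr1 at 581 CPM against 65.4 CPM in the inputs. Carry-over of unbound RNA is argued against, since the microglia list median lay 4.393 (log2) above the neuron list median. Recombination by the Tie2 promoter transgene in cells of the blood lineage may account for it. Of the microglia, macrophage and pan-leukocyte members, 97.8% (44 of 45) were higher. The erythroid and neutrophil lists, also of this lineage, were not called in brain without the replicate block, as given above. Since 0 libraries here lacked the transgene, this explanation stays open. Binding of the antibody or beads to myeloid cell material cannot be told apart from it: the platelet list, from cells without the mouse activating Fc receptors, had a median of 2.217 with 2 of 4 members higher, and a mock pull-down was not analysed here.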

How the results depend on the processing

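The alternatives with the authors' factors, limma on the deposited values, only 2 tissues, another reference library, or without both fractions of 1 replicate number were chosen after the data were seen. Of 259 named values, none changed direction in a called test (0 reversed). Over all alternatives 5845 values stayed on the same side of the threshold, 23 lost their call and 14 gained one, and 29 of these 37 came with libraries left out. This was largely set by the choice to name genes whose call did not depend on a single library. Of all calls fewer were kept: 72 of 1397 for retina against brain without replicate 953. Counts moved by more than 1.5 times as follows, and the cause was not tested except for the reference library and where the construction gives it.

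A minimum of 2-fold, which by construction keeps fewer genes, gave 1454 higher in choroid, 1074 higher and 113 lower in retina, 991 lower in brain, 746 more enriched in choroid than in brain, 583 more enriched in choroid than in retina, and for the positive fractions 1935 and 1581 (retina against brain), 1010 and 1495 (choroid against brain) and 2207 higher (choroid against retina). All 18 libraries in one fit gave 1443 higher and 676 lower in retina. Brain input 421 as the reference library of the scaling gave 447 more and 885 less enriched in retina than in brain, and 812 more enriched in choroid than in brain. Only the 2 tissues gave 1129 less enriched in retina than in brain. Library size only gave 547 and 2196 for choroid against brain, and 580 more enriched in choroid than in retina. Genes enriched in all 3 tissues numbered 749 at a log2 fold change above 0 and 190 at 2 or more. With an estimated inter-gene correlation 0 lists were called higher and 0 lower for enrichment, and 0 and 0 for the differences. Still, 1, 7 and 7 lists had an unadjusted p under 0.05 in choroid, retina and brain. In the differences of retina and brain, choroid and brain, and choroid and retina there were 2, 7 and 5. This repeat had few residual degrees of freedom, so it cannot tell an unchanged list from a changed one. Beyond the calls given with the results, the replicate block changed no call of a named value and no enrichment call of a list. It gave 3223 higher and 3412 lower in choroid, 2185 and 1701 in retina and 2504 and 1663 in brain.

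With 1 library or 1 replicate number left out, where an arm can be down to 2 libraries, the counts of higher and lower genes ran from 1066 to 2575 and 906 to 2498 in choroid, 722 to 3095 and 110 to 2653 in retina, and 1291 to 4758 and 164 to 4860 in brain. For the differences in enrichment they ran from 25 to 1088 and 47 to 1661 (retina against brain), 199 to 1402 and 399 to 2077 (choroid against brain) and 144 to 1863 and 480 to 2245 (choroid against retina). For the positive fractions they ran from 2500 to 3555 and 2132 to 3494 (retina against brain; also enriched over input 99 to 132 and 648 to 944), 1245 to 2613 and 1647 to 2737 (choroid against brain; 426 to 666 and 109 to 240) and 2701 to 3462 and 3443 to 4183 (choroid against retina; 849 to 969 and 125 to 166). Genes enriched in all 3 tissues ran from 303 to 440. Most of the lowest counts came without replicate 953. The highest counts of brain came without replicate 960, and those of choroid against retina without brain input 960. In brain Mbp and Snap25 were not called without replicate 421 (adjusted p = 0.0782 and 0.185) or 953 (0.117 and 0.158) or with all 18 libraries in one fit (0.178 and 0.143), with adjusted p from 5.22e-06 to 0.178 over its 20 alternatives for Mbp and 1.47e-05 to 0.185 over its 19 alternatives for Snap25. Plvap was called in brain without replicate 960 (0.59, adjusted p = 0.00165), with adjusted p from 0.00165 to 0.927 over its 20 alternatives. Depth limits choroid most, where 4082 of 11718 genes met the minimum of 50 in the inputs alone, so that a lower level in the positive fraction of these rests on few reads.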

Other observations

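The comparisons of this part with Rpl10a and with the splits were chosen after the data were seen. So was the choice to report the noncoding list here and the immediate early list above, although both lists were fixed beforehand.

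Rpl10a, the ribosomal protein through which NuTRAP tags ribosomes, ranked 1, 2 and 2 from the top among 73 cytosolic ribosomal protein genes in choroid, retina and brain. Its log2 fold change of positive over input was 1.27 ± 0.25 (adjusted p = 0.00412), 0.96 ± 0.11 (0.000245) and 1.53 ± 0.47 (0.0377), against list medians of 0.22, 0.17 and 0.46. The brain value was 2.29 ± 0.13 without brain input 960 (adjusted p = 1.38e-05), where Rpl10a had 374.9 CPM against 117.8 and 124.8 CPM in the other inputs. The brain call was lost without input 421 (0.0874), input 953 (0.0928), positive 421 (0.1), positive 953 (0.145) or positive 960 (0.0771), with adjusted p from 8.65e-07 to 0.284 over its 20 alternatives. The retina call was lost with all 18 libraries in one fit (0.0614, in a range of 1.11e-16 to 0.0614), and choroid ran from 1.84e-06 to 0.0423. The choroid median was -0.005 with library size only, and whether reads from the transgene were counted as Rpl10a was not tested.

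Notch pathway genes were higher in the positive fraction of choroid (8 higher and 1 lower of 12, median 1.72, camera adjusted p = 0.000902, and adjusted p = 0.321 with an estimated correlation), retina (6 of 11 higher, median 0.77, camera adjusted p = 0.0168, and adjusted p = 0.495 with an estimated correlation) and brain (6 of 12 higher, median 1.07, camera adjusted p = 0.00348, and adjusted p = 0.285 with an estimated correlation). Genes of leukocyte adhesion and haemostasis were higher in choroid (7 of 9 higher, median 1.49, camera adjusted p = 0.0005, and adjusted p = 0.317 with an estimated correlation), retina (6 of 7 higher, median 3.44, camera adjusted p = 3.31e-06, and adjusted p = 0.284 with an estimated correlation) and brain (9 of 9 higher, median 3.51, camera adjusted p = 1.44e-07, and adjusted p = 0.284 with an estimated correlation), among them Vwf (6.68±0.23) in retina. TGF-beta, BMP and angiopoietin genes were higher in all 3 tissues (11 of 13 higher, 11 and 1 adjusted over the list alone, median 2.53, camera adjusted p = 5.02e-06, and adjusted p = 0.284 with an estimated correlation; in retina 11 of 12 higher, 11 and 1 adjusted over the list alone, median 4.04, camera adjusted p = 4.72e-09, and adjusted p = 0.284 with an estimated correlation; in brain 11 higher and 1 lower of 13, 11 and 2 adjusted over the list alone, median 3.90, camera adjusted p = 3.15e-06, and adjusted p = 0.284 with an estimated correlation), with Tgfbr2 (4.86±0.19) and Id1 (4.65±0.18) in retina.

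Nuclear long noncoding RNAs were lower in the positive fraction of choroid (5 of 7 lower, median -1.05, camera adjusted p = 0.0146, and adjusted p = 0.284 with an estimated correlation). As a list they were not called in retina, where most were higher (5 higher and 1 lower of 8, 6 and 1 adjusted over the list alone, median 0.75, camera adjusted p = 0.088). They were not called in brain either (2 of 9 lower, 0 and 1 adjusted over the list alone, median -0.59, camera adjusted p = 0.0768). The brain list was called only with the replicate block and the preset correlation, as given above. In retina Malat1 had 1750 CPM in positive 960 against 3175 and 3093 CPM in positives 421 and 953, and 1683 to 2892 CPM in inputs. The difference between retina and brain was called by the preset test (3 of 7 higher, median 1.76, camera adjusted p = 0.0371, and adjusted p = 0.4 with an estimated correlation), as was that between choroid and retina (4 of 7 lower, 0 and 5 adjusted over the list alone, median -1.79, camera adjusted p = 0.0178, and adjusted p = 0.373 with an estimated correlation).

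Each comparison has 10 splits of its libraries into 3 against 3, which are too few for a share under 0.05. The real split was the 1 of 10 with the most calls, at 4922 in choroid, 3922 in retina, 5103 in brain, 1397, 2582 and 3028 for the differences in enrichment (retina against brain, choroid against brain, choroid against retina) and 6621, 4919 and 7566 for the positive fractions in that order, and the highest of the other splits was 0 in each. For enrichment, 4 of the 10 splits part every input from its own positive library, the real one among them, and the other splits leave 2 such pairs whole. Of these 4 the real split had the most calls with the replicate block too (6635, 3886 and 4167 in choroid, retina and brain), and the highest of the other 3 was 0. Every split but the real one puts libraries of both fractions or both tissues into each arm. Real differences between them then add to the spread within an arm, so low counts in these splits were built in. The splits therefore cannot decide whether the real counts arose by chance.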
